A study of Mus musculus with 6 samples.

How the data were processed

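Total RNA from 6 samples of mouse NIH3T3 fibroblasts was labelled with biotin and hybridised to Affymetrix expression arrays, 3 from cells described as tethered and 3 as untethered. All cells belonged to clone M, which carries multiple insertions of the lac operator (lacO), the DNA element bound by the lac repressor. The labels place the insertion at the nuclear periphery in tethered cells and centrally in untethered cells. Cells were grown to about the same confluency in the same serum-containing medium, per the labels. The labels do not say whether arrays of 1 group came from separate cultures passaged apart. P-values of single probe sets therefore measure the spread between these samples, part of which may be technical.

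The deposited values are intensities on a linear scale, 1 per probe set and array, as the authors processed them. The software that summarised the probes and the method of scaling are not given in the sources used here. The median intensity differed by 1.76% between the lowest and the highest array and the lower quartile by 1.58%, so the values were taken as already brought to a common scale. The 95th percentile differed by 16.4%. No detection calls were used here, so no probe set was called present or absent, and the number of arrays limits the precision.

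Probe sets were named from the platform annotation, with symbols updated through the gene identifier to a mouse RefSeq gene table of assembly GRCm38.p6. Of 45101 probe sets, 64 were hybridisation or RNA-quality controls and were left out of the tests. Of the others, 34945 had 1 gene symbol, 932 had several and 9160 had none, and 99.4% of the identifiers of probe sets with 1 symbol were found in the gene table. No gene was named from a probe set with several symbols. The gene table served for names and for the order of neighbouring genes. None of its coordinates is given, because no genome build is named for the array values.

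Intensities below 16 were set to 16 and log2 was taken. Probe sets whose mean log2 intensity lay above the median of all probe sets were tested, which left 22518 probe sets for 11846 genes. Each was compared between the groups with limma's linear model and empirical Bayes moderation (limma 3.58.1, R 4.3.3), with no covariate and all 6 arrays. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. A looser count took probe sets at least 1.5-fold different with an unadjusted p under 0.01. All tests were two-sided. A log2 fold change is tethered minus untethered, and errors of group means are standard deviations over 3 arrays.

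For tests of groups of genes, the brightest probe set stood for each gene. The camera test with a preset correlation of 0.01 compared each of 28 gene lists with the other genes. Lists with fewer than 5 tested members were left out. Its p-values set genes against genes, so they do not measure the spread between arrays as those of single probe sets do. The same test was run with an estimated correlation, and fry was run beside it. Windows of 11 neighbouring genes, moved 1 gene at a time along each chromosome, and whole chromosomes were tested in the same way. These scans were made over all chromosomes because the position of the insertions is not given in the sources used here. Each list's median was also set against 10000 random lists of the same size matched on mean signal.

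Genes were named by a fixed rule. It took up to 12 probe sets per direction past the adjusted threshold with 1 symbol and groups that did not overlap, or, where too few passed, those with the smallest unadjusted p under the same conditions. It added up to 4 members with the smallest p of each list described, the members of the 3 windows with the smallest p in each direction, and the envelope and co-repressor genes Emd, Lmna, Lmnb1, Lmnb2, Lbr, Tmpo, Hdac3 and Ncor1. Ncor1 was named by 0 probe sets of the annotation and was not tested. The groups, the tests, the lists, the naming rule and the alternatives were fixed before the data were examined, except where a choice is said to have been made afterwards.

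The procedure was tested on simulated data. Arrays were simulated from the real means and residual spread of the 22518 probe sets, with 200 of them changed. The comparison of tethered with untethered arrays recovered 32% of 1.5-fold changes, 68% of 2-fold, 90% of 4-fold and 95.5% of 8-fold changes. In these simulated arrays 3, 7, 11 and 13 unchanged probe sets were called, in the same order. The same changes were then added to 200 probe sets of the real tethered arrays. There 0% of 1.5-fold, 66% of 2-fold, 94% of 4-fold and 98% of 8-fold changes were recovered, and 0 probe sets without an added change were called. Such an addition leaves the p-values of the other probe sets unchanged, at 0.001063 or above. These are too large to be called beside 200 changed probe sets, so this 0 was fixed in advance and does not measure false calls. Shifting 1 window of 11 genes by -0.25 on the log2 scale in the real tethered arrays led to its call in 100% of 40 windows, with the preset correlation. All 11 genes were given the same shift. A change in a few neighbouring genes, or an uneven change, was not simulated, so the window scan may miss it.

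Alternatives were no filter, only probe sets above the 0.75 quantile of mean signal, a floor of 32, quantile normalization, centring on array medians, array weights, trended and robust variance, unmoderated tests per probe set, 1 or the mean of all probe sets per gene, the replicate number as a block, other window sizes and leaving out each array in turn. Leaving out both arrays numbered 1 was added after seeing the data. Figures were drawn with matplotlib 3.10.9.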

Results

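Gene expression was measured on 6 arrays of NIH3T3 cells, an immortalised mouse fibroblast line, in a clone (clone M) with lacO arrays inserted in its genome. In 3 samples the insertion was held at the nuclear periphery (tethered) and in 3 it lay centrally in the nucleus (untethered). The median intensity per array lay between 482.4 and 490.9. Correlations of log2 intensity ran from 0.92 to 0.987 between arrays of the same group and from 0.928 to 0.991 between arrays of different groups. The first principal component held 62.1% of the variance and set both arrays numbered 1, 1 from each group, at -30.3 and -38.0, with the other 4 between 5.49 and 26.6.

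The study asked for the transcription state of genomic regions that are brought to the inner nuclear membrane. Between tethered and untethered cells, the genes with the smallest p-values were lower in tethered cells, and none passed the adjusted threshold. Ier3, an immediate early gene, had a log2 intensity of 12.55 ± 0.11 (SD, n = 3) in tethered and 13.12 ± 0.13 (SD, n = 3) in untethered cells, a log2 fold change of -0.57 with a standard error of 0.098. Ralgps2, an exchange factor for Ral GTPases, stood at -0.69 (SE 0.12), and Klf6, a zinc-finger transcription factor, at -0.67 (SE 0.13). Fgfr1, a fibroblast growth factor receptor, stood at -0.72 (SE 0.16). Nr3c1, the glucocorticoid receptor, gave -0.34 and -0.31 on its 2 probe sets chosen by the rule. Further values below 0 with groups that did not overlap belonged to Parp3 (-0.53), Ifit2 (-0.46), AI413582 (-0.41), Zfp445 (-0.37), Kitl (-0.29), which encodes stem cell factor, and Tusc1 (-0.28).

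Among the genes named by the rule, the largest values above 0 were smaller in size than the largest below 0. Timp3, an inhibitor of matrix metalloproteinases, had a log2 fold change of 0.27 (SE 0.063), from 11.79 ± 0.05 to 12.06 ± 0.03 (SD, n = 3 each). Synj2, Txk, Ankmy2 and Trip12 lay between 0.29 and 0.30, and Sgms2, Upk1b, Ubr1, Ccdc82, Lce1a1, Osbpl6 and Leng9 between 0.20 and 0.27. None of these genes passed the adjusted threshold either. Probe sets of 1 gene did not always move together. The 5 probe sets of Klf6 ran from -0.08 to -0.68, and a Parp3 probe set stood at 0.02 while the other two were at -0.43 and -0.53.

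Limma called 0 of 22518 probe sets, with a smallest adjusted p of 0.9994. At an unadjusted p under 0.05 there were 536 probe sets, 160 higher and 376 lower in tethered cells, where chance alone would give 1125.9. With quantile normalization the same count was 530, with 252 higher and 278 lower, so the excess of lower values depended on the scaling. An unmoderated test per probe set gave 887 probe sets at an unadjusted p under 0.05 and 0 after adjustment. These tests held no term for the replicate number, so the spread between numbers counted as residual spread and can lower such counts. A count below chance therefore does not show that the groups are alike. In 8.16% of probe sets the groups did not overlap, where chance gives 10%. The looser count held 6 probe sets, all lower in tethered cells, of Ralgps2, Klf6 (2 probe sets), Fgfr1, Abtb2 (-0.60, SE 0.15) and Atp6v0a2 (-0.60, SE 0.16); Abtb2 and Atp6v0a2 were named after their values were seen. This count was 64 without both arrays numbered 1 (6 higher and 58 lower, chosen after seeing the data), 82 without tethered replicate 1 (5 higher and 77 lower) and 1 without tethered replicate 2. The direction was mixed without untethered replicate 3 (28 higher and 36 lower) and without untethered replicate 2 (3 higher and 3 lower).

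Of the envelope and co-repressor genes fixed by the naming rule and tested, none passed the adjusted threshold. All but Lmnb1 differed by less than the standard error of the difference. Emerin (Emd), an inner nuclear membrane protein, had a log2 fold change of -0.18 (SE 0.23). Lamin A/C (Lmna) stood at -0.11 (SE 0.28), lamin B1 (Lmnb1) at 0.14 (SE 0.13) and lamin B2 (Lmnb2) at 0.15 (SE 0.16). The lamin B receptor (Lbr) stood at -0.11 (SE 0.35) and Tmpo, which encodes the LAP2 proteins, at -0.03 (SE 0.23), with a value above 0 after quantile normalization (0.018). Hdac3, a histone deacetylase, stood at -0.09 (SE 0.15). The list of 24 lamina and envelope genes, with Syne2 (0.14) and Lemd3 (-0.21) among its members of smallest p, had a median of -0.03 while camera's direction was higher, with an adjusted p of 0.80. Of 24 genes for repressive chromatin factors, 20 had values below 0, among them Sap30 (-0.44) and Ehmt2 (-0.15), with a camera adjusted p of 0.466. The median of the chromatin list lay at percentile 6.59 of random lists matched on mean signal. With 1 array left out Sap30 ran from -0.58 to -0.24 and Ehmt2 from -0.18 to -0.08. In both lists 0 members passed, adjusted over the list alone or over all genes.

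Immediate early genes, which respond within minutes to growth factors and stress, were lower in tethered cells as a group. Of 19 members, 18 had values below 0 and the median log2 fold change was -0.545 (camera, adjusted p = 1.003e-06). The call was lost with an estimated correlation (adjusted p = 0.705), and without both arrays numbered 1 (chosen after seeing the data) the median was -0.27. Egr1, a zinc-finger transcription factor, stood at -2.15 (SE 0.87), Fos at -1.52 (SE 0.55) and Junb at -1.28 (SE 0.47), and the last pair encode AP-1 subunits. Egr1 was named after its values were seen. With 1 array left out Egr1 ran from -2.77 to -1.31, Fos from -2.07 to -1.36, with no value without untethered replicate 1, where it fell below the filter, and Junb from -1.68 to -0.76, the last without untethered replicate 1. Without both arrays numbered 1 they stood at -0.80, -0.79 and -0.59. Adjusted over the list alone, 1 member passed, Ier3, and 0 passed over all genes. The mean deviation of the list from its 6-array mean was 0.85 in untethered replicate 1, 0.29 in untethered replicate 2 and -0.12 in untethered replicate 3, against -0.51, -0.34 and -0.18 in tethered replicates 1, 2 and 3. The 5' minus 3' signal of the transferrin receptor control, a measure of RNA quality, was -2.81, -3.07 and -1.52 in the untethered and -2.09, -1.67 and -1.55 in the tethered arrays, in the same order. The 5' signal of the 18S ribosomal RNA control did not overlap between the groups, at 10.74 ± 0.23 in tethered and 11.79 ± 0.56 in untethered arrays (log2, SD, n = 3 each; exact permutation p = 0.1). The GAPDH 5' minus 3' signal did not overlap either, at 0.089 ± 0.0066 in tethered and 0.018 ± 0.070 in untethered arrays (log2, SD, n = 3 each; exact permutation p = 0.1). An exact permutation test of the list's mean gave p = 0.1, the smallest that 3 arrays against 3 allow.

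**Figure D1:**
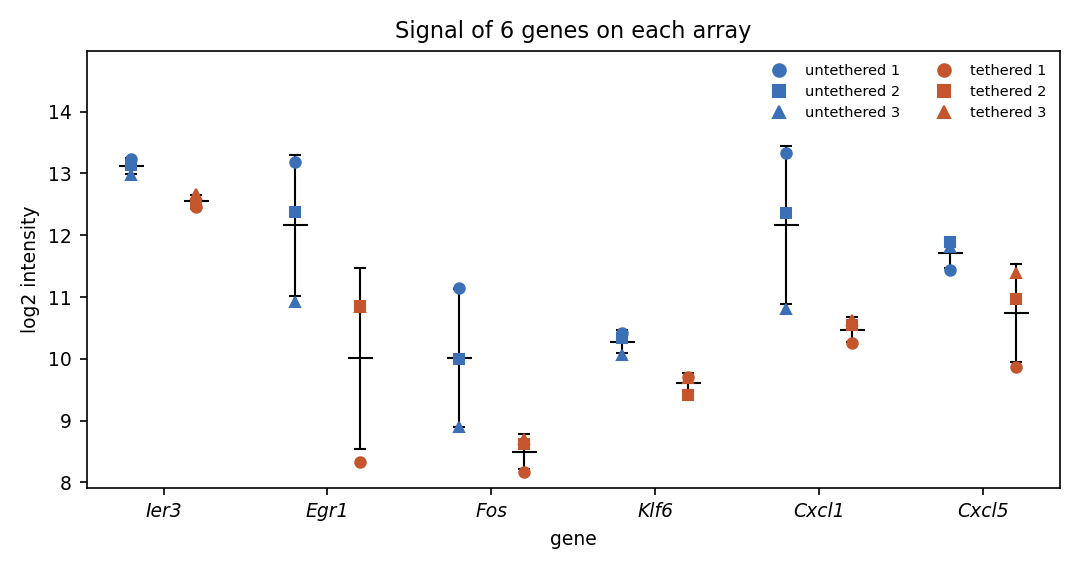
Log2 intensity of 6 genes (horizontal axis) on each array, for 1 probe set per gene; colours are the groups, shapes the replicate numbers, and black bars the mean and standard deviation of 3 arrays. For Egr1, Fos and Cxcl1 the untethered arrays spread over more than 2 log2 units, with standard deviations of 1.14, 1.12 and 1.27. In the tethered arrays the standard deviations of these genes are 1.46, 0.28 and 0.20. For Ier3 they are 0.13 in untethered and 0.11 in tethered arrays.

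Chemokines and NF-kappaB target genes were lower as a group too, with 13 of 16 values below 0, a median of -0.17 and a mean of -0.50 (camera, adjusted p = 0.0226; adjusted p = 0.705 with an estimated correlation). Cxcl1, a neutrophil chemoattractant, stood at -1.70 (SE 0.61) on its brightest probe set and at -3.14 and -1.29 on the others. Cxcl5 stood at -0.97 (SE 0.39), Ccl7 at -0.71 (SE 0.29) and Nfkbia, which encodes the inhibitor of NF-kappaB, at -1.23 (SE 0.52). With 1 array left out Cxcl1 ran from -2.38 to -1.11 and Nfkbia from -1.80 to -0.72, smallest without untethered replicate 1, and Cxcl5 from -1.29 to -0.53 and Ccl7 from -0.89 to -0.43, smallest without tethered replicate 1. Without both arrays numbered 1 Cxcl1 stood at -1.001, Nfkbia at -0.63, Cxcl5 at -0.67 and Ccl7 at -0.24. Adjusted over the list alone, 0 members passed. The exact permutation test of the list's mean gave p = 0.1, the smallest possible. The list had a median of -0.11 and an adjusted p of 0.434 without untethered replicate 1, the array with its highest mean deviation (0.58), a median of -0.29 and an adjusted p of 0.0061 without untethered replicate 2, and a median of -0.13 and an adjusted p of 0.162 without both arrays numbered 1 (chosen after seeing the data). Untethered replicates 1 and 2, with the highest chemokine means, also had the lowest transferrin receptor 5' minus 3' signals (-2.81 and -3.07). Among 12 interferon-stimulated genes, 6 values lay above and 6 below 0 (adjusted p = 0.888), and Ifit2 alone passed when adjusted over the list alone, with 0 over all genes.

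Hypoxia and glycolysis genes were lower in tethered cells, with 22 of 23 values below 0 and a median of -0.23 (camera, adjusted p = 9.92e-06; adjusted p = 0.705 with an estimated correlation). The exact permutation test of this list's mean over arrays gave p = 0.2. Adm, which encodes adrenomedullin, stood at -0.69 (SE 0.29) and at -0.45 without tethered replicate 2. Pfkl, a phosphofructokinase, stood at -0.41 (SE 0.18) and P4ha1, a collagen prolyl hydroxylase, at -0.405 (SE 0.17). Egln3, an oxygen-sensing prolyl hydroxylase, stood at -0.34 (SE 0.14). With 1 array left out Pfkl ran from -0.59 to -0.27, P4ha1 from -0.58 to -0.26 and Egln3 from -0.46 to -0.24. The call was lost without untethered replicate 1 (median -0.10, adjusted p = 0.0619) and without both arrays numbered 1 (median -0.19, adjusted p = 0.0725, chosen after seeing the data), and the median was -0.36 without untethered replicate 3. The list's mean deviation was highest in untethered replicates 1 (0.31) and 2 (0.18), the arrays with the lowest transferrin receptor 5' minus 3' signals (-2.81 and -3.07), and was -0.11 in untethered replicate 3 (-1.52).

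The cholesterol synthesis list had 16 of 18 values below 0 and a median of -0.15 (camera, adjusted p = 0.0226). Hmgcs1, an enzyme early in the pathway, stood at -0.38 (SE 0.21) and Insig1 at -0.48 (SE 0.34). With 1 array left out Hmgcs1 ran from -0.61 to -0.26 and Insig1 from -0.85 to -0.27. The lysosomal list had 19 of 22 values below 0 and a median of -0.17 (camera, adjusted p = 0.030). Gla, alpha-galactosidase A, stood at -0.52 (SE 0.23) and Lamp2 at -0.21 (SE 0.096). With 1 array left out Gla ran from -0.76 to -0.30 and Lamp2 from -0.29 to -0.16. The mitochondrial respiratory chain list had 60 of 67 values below 0, a median of -0.09 (camera, adjusted p = 0.025) and Ndufv3, a complex I subunit, at -0.16 (SE 0.076). Random lists matched on mean signal had medians mostly between -0.077 and -0.019, so a median below 0 was usual at this signal. The mitochondrial median lay at percentile 0.83 of them. With an estimated correlation the cholesterol, lysosomal and mitochondrial lists each had an adjusted p of 0.996. In none of them did a member pass, adjusted over the list alone or over all genes. Exact permutation tests of their means over arrays gave p = 0.5, 0.4 and 0.6, in the same order. Without tethered replicate 2 the cholesterol median was -0.03 (adjusted p = 0.746) and the lysosomal median -0.06 (0.171). The cholesterol call was also lost without untethered replicate 2 (median -0.11, adjusted p = 0.055), untethered replicate 3 (-0.115, 0.103) or tethered replicate 3 (-0.18, 0.0799), the last with a larger median than the main one. The lysosomal call was lost without untethered replicate 1 (-0.10, 0.604) or tethered replicate 3 (-0.099, 0.298). With 1 array left out the medians ran from -0.27 to -0.03 for the cholesterol and from -0.30 to -0.06 for the lysosomal list. Without both arrays numbered 1 (chosen after seeing the data) they were larger, at -0.375 (adjusted p = 2.052e-08) and -0.25 (0.001225), and between the arrays numbered 1 the means of both lists were higher in the tethered array, by 0.23 and 0.040. The mitochondrial median turned to 0.03 without tethered replicate 1 (adjusted p = 0.344), and the call was lost without untethered replicate 2 (median -0.02, adjusted p = 0.601) or untethered replicate 3 (-0.03, 0.426), or without both arrays numbered 1 (-0.11, 0.0508). After quantile normalization the mitochondrial median was -0.04 (adjusted p = 0.03005), while the median of all probe sets moved from -0.016 to 0.00929, and with arrays centred on their medians the mitochondrial median was -0.08 (0.01545). After quantile normalization the lysosomal median was -0.12 (adjusted p = 0.0821).

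Endothelial marker genes, 5 of which were tested, were the 1 list called higher, with a median of 0.11 (adjusted p = 0.00944; adjusted p = 0.705 with an estimated correlation). Pecam1 stood at 0.18 (SE 0.068), Flt1 at 0.13 (SE 0.065) and Kdr at 0.11 (SE 0.059), all with mean log2 intensities under 9.85, and 0 members passed when adjusted over the list alone. Without untethered replicate 3 the camera adjusted p was 0.149 and the median 0.10. The list's mean deviation was lowest in that array (-0.10), against -0.01 and -0.02 in untethered replicates 1 and 2. It lay between 0.03 and 0.06 in the tethered arrays, and its exact permutation test gave p = 0.1, the smallest possible. With the mean of a gene's probe sets the median was 0.0585 (adjusted p = 0.0144).

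Of 28 lists, 26 had at least 5 tested members. Of these, 7 were called, 0 with an estimated correlation and 0 by fry. Other splits of the 6 arrays into 3 and 3 called from 6 to 14 lists with the preset correlation. The lists not called were S phase (adjusted p = 0.983), G2 and M phase (0.983), p53 targets (0.466), extracellular matrix (0.458), actin cytoskeleton and SRF targets (0.87), unfolded protein response (0.888), amino acid response (0.717), heat shock (0.979), oxidative stress (0.12), TGF-beta and BMP response (0.983), Wnt pathway (0.547), ribosomal proteins (0.979), proteasome (0.827), muscle markers (0.547), adipocyte markers (0.80) and macrophage markers (0.80). Epithelial and neural markers had 4 and 2 tested members and were not tested as lists.

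**Figure D2:**
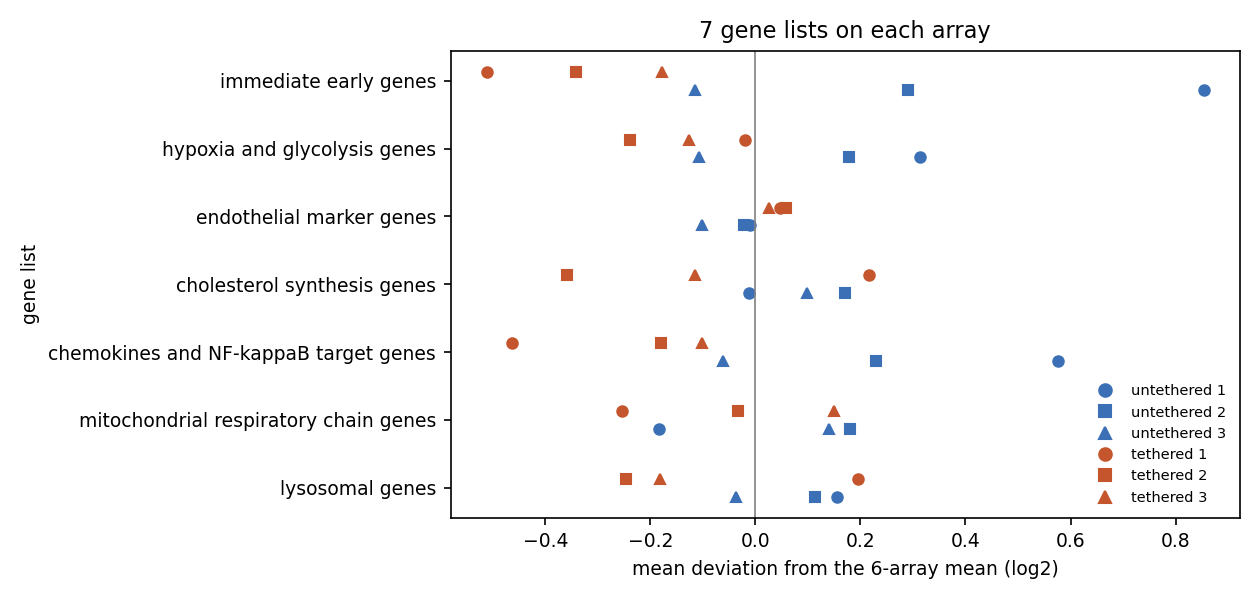
Mean deviation of each list's genes from their mean over the 6 arrays (log2, horizontal axis) for the 7 called lists (vertical axis), 1 point per array; colours are the groups and shapes the replicate numbers. For immediate early genes the untethered arrays run from -0.12 to 0.85 and the tethered arrays from -0.51 to -0.18. The groups overlap for hypoxia, cholesterol, lysosomal and mitochondrial genes.

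The last comparison concerned neighbouring genes, since the study is about genomic regions. Of 11576 windows of 11 genes, 0 were called, with a smallest adjusted p of 0.663. At an unadjusted p under 0.05 there were 660 windows, 331 lower and 329 higher, where chance alone would give 578.8. The windows overlap and are not independent.

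The lower window of smallest p lay on chromosome 10 and ran from Herc4 to Slc16a9, with 11 of 11 values below 0 and a median of -0.15. Its unadjusted p from camera was 0.000462. It holds Jmjd1c and Arid5b, which encode chromatin proteins, and Cdk1, the mitotic kinase. The next lay on chromosome 12 from Arhgap5 to Ppp2r3c, with 9 of 11 values below 0 (median -0.17), and on chromosome 13 from Akr1e1 to Zmynd11, with 10 of 11 (median -0.13) and Klf6 among its genes. The higher windows of smallest p lay on chromosome 17 from Ppil1 to Zfand3 (median 0.09, 2 of 11 values below 0), on chromosome 1 from Dusp23 to Chml (0.08, 1 of 11) and on chromosome 15 over the keratin genes from Krt86 to Krt78 (0.07, 1 of 11). None of these windows passed the adjusted threshold. By whole chromosome, 0 of 20 were called, with a smallest adjusted p of 0.896 and medians from -0.04 to -0.01. Camera gave 0 chromosomes at an unadjusted p under 0.05.

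**Figure D3:**
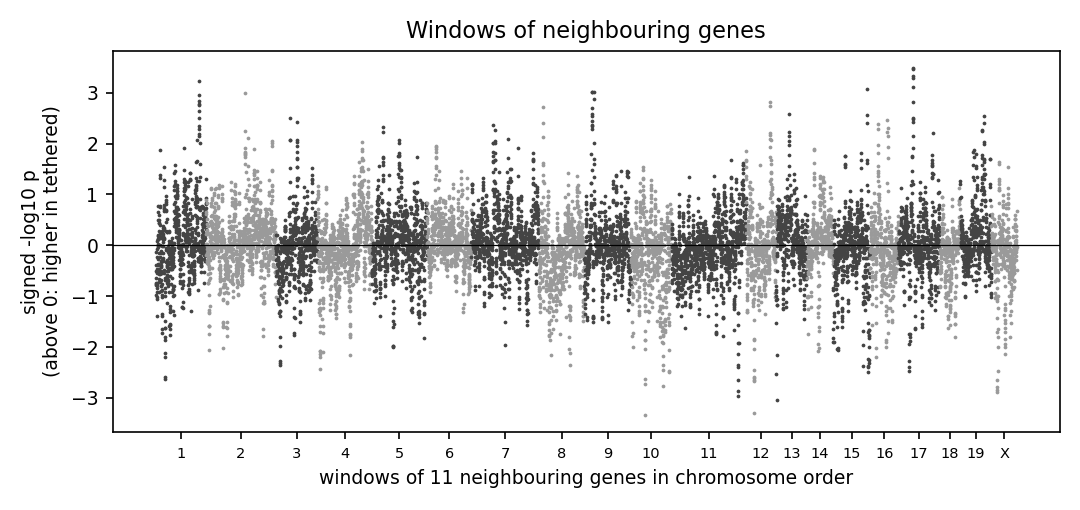
Signed -log10 of camera's unadjusted p (vertical axis; above 0 the window was higher in tethered cells) for windows of 11 neighbouring genes in order along chromosomes 1 to 19 and X (horizontal axis, shades alternate by chromosome). The 11576 windows scatter to both sides of 0, 331 lower and 329 higher at p under 0.05, and none passed adjustment.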

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

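Leaving out both arrays numbered 1 was chosen after seeing the data. The counts of called probe sets, windows and chromosomes stayed at 0 under every alternative run for each, leave-one-out fits included (0 to 0). The 6 probe sets of the looser count became 19 without a filter (6 higher, 13 lower), 2 above the 0.75 quantile of mean signal, 20 with arrays weighted, 64 without both arrays numbered 1 and 0 at 2-fold; leaving out 1 array at a time gave 1 (without tethered replicate 2) to 82 (without tethered replicate 1). The 7 called lists (1 higher, 6 lower) became 0 with camera's estimated correlation and 0 by fry. With 1 array left out there were 5 to 12 called lists, 12 without tethered replicate 1 (5 higher, 7 lower). Without tethered replicate 3 there were 9 (3 higher, 6 lower). The cause of these moves was not tested, except that a stricter fold, a filter or fewer arrays changes what can be counted.

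The immediate early list kept its direction and call under the alternatives run for lists (filters, scalings, array weights, the block, the mean of probe sets, arrays left out) except the estimated correlation (adjusted p = 0.705) and fry (0.419), with medians of -0.65 to -0.39 when 1 array was left out and -0.27 without both arrays numbered 1. Over the 7 lists, 27 values were in the main direction but no longer past the threshold, and 1 turned, mitochondrial genes (-0.20 to 0.029 with 1 array left out). Weighting the arrays ended the calls of chemokines (median -0.29, adjusted p = 0.186) and mitochondrial genes (-0.09, 0.0846), and the 0.75 quantile filter those of lysosomal (-0.17, 0.0795) and mitochondrial genes (-0.09, 0.0733), with medians no smaller than the main ones; under that filter the chemokine median was -0.47 (0.0355). Of the named probe sets, 10 values changed sign, each of a gene that was never called. Tmpo stood at 0.018 after quantile normalization and Lmna at 0.082 without both arrays numbered 1. With 1 array left out, Emd ran from -0.38 to 0.035, Lmna from -0.29 to 0.20, Lbr from -0.45 to 0.10, Tmpo from -0.19 to 0.15 and Hdac3 from -0.21 to 0.011. Lmnb1 (0.034 to 0.23) and Lmnb2 (0.016 to 0.28) kept their sign but moved in size. The cause was not tested.

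With the replicate number as a block, called probe sets, windows and chromosomes stayed at 0. The looser count was 16 (0 higher, 16 lower) and the called lists 9. The numbers do not pair the arrays by the rule set beforehand: deviations of same-numbered arrays from their group means correlated at 0.71, 0.075 and 0.711. Not every array correlated best with its own number, as tethered replicate 2 was closest to untethered replicate 3 (0.365). Signal over background was not measured apart from the floor and filter, so changes in dim genes are limited by unmeasured background.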

Other observations

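The comparison of arrays by their number, the RNA-quality test and the test without both arrays numbered 1 were chosen after results on these arrays were seen. Apart from the study's groups, both arrays numbered 1, 1 tethered and 1 untethered, differed from the other 4 in the genes of the cell cycle. In a limma model with the group as a term, 1542 of 11846 genes passed an adjusted p under 0.05, 228 higher and 1314 lower in the arrays numbered 1. Of 23 G2 and M phase genes 22 were lower, with a median log2 difference of -1.50, among them Birc5 (-1.78, SE 0.075), Aurkb (-1.51, SE 0.070) and Cenpa (-1.62, SE 0.075), which act in chromosome segregation. Of 22 S phase genes 19 were lower, among them Tk1 (-2.22, SE 0.072) and Rrm2 (-2.44, SE 0.087), which serve DNA replication. Proteasome genes were lower in 28 of 36 members, among them Psma1 (-1.07). Ccnd1, cyclin D1, stood at -1.60, and Cck, which encodes cholecystokinin, had log2 intensities of 7.21 and 7.19 in the arrays numbered 1, below the lower quartile of every array, and of 11.14 to 11.73 in the others. With an estimated correlation 0 lists passed (adjusted p = 0.437 for G2 and M phase, S phase and proteasome genes).

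Genes of the unfolded protein response were higher in the arrays numbered 1, in 11 of 17 members, with a median of 0.74 (adjusted p = 0.582 with an estimated correlation). Ddit3, a stress transcription factor, stood at 2.74 (SE 0.39), Pdia4, a protein disulphide isomerase, at 1.54 (SE 0.12) and Herpud1 at 1.05 (SE 0.14). Of 21 amino acid response genes 7 were higher, among them Trib3 (1.61) and Chac1 (2.11), and of 22 lysosomal genes 4 were higher (adjusted p = 0.59 and 0.582 with an estimated correlation). Atf3 stood at 2.76. In the same arrays Emd (-0.54, SE 0.092), Lbr (-0.81, SE 0.14) and Tmpo (-0.50, SE 0.072) were lower, as were 11 of the 24 lamina and envelope genes.

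The separation of the arrays numbered 1 was tested against scaling and against a property of any same-numbered pair. After quantile normalization 1764 genes passed, more than the 1542 before (684 higher and 1080 lower, against 228 and 1314), so scaling alone would not account for it. The arrays numbered 3 gave 496 genes against the other 4 and the arrays numbered 2 gave 0, both fewer than 0.5 of that count. Number 1 had been picked because it lay farthest out on the first principal component, so fewer genes for the others, the outcome named beforehand as evidence against a property of any pair of arrays with the same number, decides nothing. The labels give the same confluency for all samples. A difference in growth state between rounds of culture may still contribute, and so may a difference in RNA handling. Neither was measured, so these stay open and no biological explanation was tested.

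The lower immediate early genes in tethered cells were weighed against technical explanations. The list's median lay at percentile 0 of 10000 random lists matched on mean signal, which argues against a trend with signal level left by the scaling of the arrays. Random lists lack the correlation of a real list, and some lists that were not called also lay far out. Extracellular matrix genes lay at 0.02 and oxidative stress genes at 99.72, while lamina and envelope genes lay at 52.6. The percentile therefore does not show that the shift itself is beyond chance. Without both arrays numbered 1 the list was still lower (camera, adjusted p = 0.0048 with the preset correlation). The median was -0.27 in place of -0.545, so the arrays numbered 1 carry a large part of the shift. Between same-numbered arrays the list's mean differed by -1.365, -0.63 and -0.063 for numbers 1, 2 and 3. The shift was thus not confined to the arrays numbered 1. The numbers do not pair the arrays, so these differences do not assign the rest to 1 number. The list's mean deviation was 0.29 in untethered replicate 2 but -0.12 in untethered replicate 3. It was -0.34 and -0.18 in tethered replicates 2 and 3. Leaving out 1 array at a time gave adjusted p from 1.421e-09 to 0.00707 with the preset correlation. The fit on all 6 arrays gave 0.705 with an estimated correlation, which was not run without both arrays numbered 1. RNA integrity differing between the groups stays open: the transferrin receptor 5' minus 3' signal was higher by 0.70 in tethered arrays (exact permutation p = 0.4, with 0.1 the smallest possible), while the GAPDH 5' minus 3' signal (0.070), the 18S ribosomal RNA 5' signal (-1.05) and its 3' signal (-0.13) differed with exact permutation p = 0.1 each, and actin 5' minus 3' (0.17) with p = 0.2. A difference between cultures in time since handling or serum contact, to which these genes respond, may also be at work, as may tethering itself, and neither was tested.

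The lower chemokines in tethered cells were weighed against 1 technical explanation. The list's median lay at percentile 0 of the matched random lists, which argues against a trend with signal level left by the scaling of the arrays. The limit given for the immediate early list holds here too. The call was lost without untethered replicate 1 (camera, adjusted p = 0.434, median -0.11 against -0.17) and with arrays weighted (0.186, median -0.29). With 1 array left out the adjusted p ran from 0.000493 to 0.434. Between same-numbered arrays the list's mean differed by -1.04, -0.41 and -0.041 for numbers 1, 2 and 3. Untethered replicate 1 had the highest mean deviation (0.58), so that array carried part of the shift. Whether RNA integrity, culture handling or tethering could account for the rest stays open. RNA integrity was not weighed for this list, though untethered replicates 1 and 2 also had the lowest transferrin receptor 5' minus 3' signals.

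The 6 arrays split into 3 and 3 in 10 ways, too few for a share under 0.05. The count of called probe sets was 0 for the study's groups, reached by 10 of 10 splits, and 409 for the highest other split, which set both arrays numbered 1 and untethered replicate 2 against the rest and points to a structure of the samples. The looser count was 6, with 683 in the highest other split and 6 of the 10 splits as large. The count of called lists was 7, with 14 in the highest other and 7 of the 10 as large. No split called fewer than 6 lists, so the count of 7 does not set the study's groups apart from other splits. Called windows and chromosomes were 0, with 1 each in the highest other and 10 of 10 as large.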
